A study of Mus musculus with 12 samples.

How the data were processed

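RNA-seq was analysed for 12 thymic T-cell lymphomas of C57BL/6 mice, 8 labelled responder and 4 labelled non-responder. Per the labels, weekly tamoxifen activated a Cre recombinase in tumour-bearing mice to reactivate wild-type p53, and the mice also carried a mutant Trp53 allele. The animals were followed by magnetic resonance imaging (MRI), and each tumour was harvested after the last scan, in which growth or shrinkage was seen. The labels call the tumours independent biological samples and give no batch, pairing or tumour size at harvest.

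The values are raw counts per Ensembl gene, deposited by the authors in 1 table of 37991 genes, and whole in every cell. Per the labels' protocols, mRNA libraries were made with a TruSeq kit and sequenced as 75-base paired-end reads, 4 libraries to a lane. The counts come from HTSeq and the authors' comparison from DESeq, per the submitters' processing notes, which give no versions. The genome build is not settled by the sources used here, since the processing notes name NCBIM37 while the extract protocol in the labels names mm10. The aligner and whether counting used the strand are not given in the sources used here, so reads where a named gene overlaps another on the opposite strand cannot be assigned. Gene symbols were matched by Ensembl identifier to the GENCODE M21 table of GRCm38. Of the 37991 identifiers, 32919 had a symbol and 5072 had none, and the latter took 3.07% ± 0.422 of the counts in responders and 3.13% ± 0.456 in non-responders (SD, n = 8 and 4). Coordinates below are GENCODE M21 positions on GRCm38, 1-based, and were not used in counting.

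The counts were used as deposited. Genes were filtered with filterByExpr, which left 18612, and scaled by trimmed mean of M values (TMM). They were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with robust dispersion, with the group as the sole term. Tests were two-sided and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Log2 fold changes are non-responder minus responder throughout, and their standard errors (SE) were derived from the F statistic. Levels are CPM, that is, counts divided by the TMM-scaled library total and brought to a common scale, and log2 CPM used a prior count of 2. Standard deviations (SD) describe the spread between tumours.

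A set of 46 gene lists was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01. The same lists were tested with an estimated correlation and with fry. For the members of each list, p-values were also adjusted over the list alone. The mean log2 CPM of each of 13 lists of other cell types, called its score, was compared between groups by an exact permutation test over all 495 splits of the 12 tumours into 8 and 4. Trp53 and 10 core targets were compared by the same permutation test. The lists, the tests, the rule for named genes and the alternatives were fixed before the data were examined, except where a choice is said to be later. The retinoic acid list was chosen because the study's paper is thought to concern retinoic acid, so it is not independent of the study.

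Named genes are Trp53 and the 10 core targets. As no gene passed the threshold, the 10 genes with the lowest p in each direction follow as values and not as calls. Predicted genes, receptor segments and identifiers with no symbol were passed over, which removed 5 genes among the higher and 0 among the lower. From each list called by camera the 4 members with the lowest p could be named, and from the retinoic acid, p53 target, BCL2 and T-lymphoma lists the 3 with the lowest p. The text names part of these.

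The alternatives were RLE and upper-quartile scaling, no filter, a filter of 1 CPM in 4 libraries, no robust dispersion, limma-voom with quality weights, and DESeq2 1.42.0. Further ones were 1 surrogate variable (sva 3.50.0), the fibroblast and macrophage scores as covariates, a threshold of 0.1, and removal of receptor-segment, mitochondrial, haemoglobin and sex-linked genes. Libraries were also thinned to the smallest, each tumour was left out in turn, and the scores were recomputed with a prior count of 0.5, with medians and with RLE scaling. The mean of the 13 scores as a covariate was added after seeing the data.

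The total count per tumour lay between 20796860 and 30265753. No pair of libraries was a repeat, since the chi-square of the counts per degree of freedom was at least 65.2 for every pair. No molecular identifiers are named in the labels, so the Wilson 95% intervals given for shares of counts cover counting error only. The procedure was tested on simulated data for this comparison, with counts drawn for the 18612 genes from the real means, library sizes and dispersions; after filtering, edgeR and limma-voom ran on 18216 of them and DESeq2 on 18612. edgeR recovered 26% of 50 genes changed 2-fold, 70% of 50 changed 4-fold, 98% of 50 changed 8-fold and 94% of 50 changed 16-fold, and called 6 of 18392 unchanged genes. DESeq2 recovered 44%, 86%, 100% and 96% at those sizes and called 72 unchanged genes, and limma-voom 22%, 68%, 96% and 94% with 5. Each gene was drawn independently around a single mean per group, so these shares do not cover subgroups among the responders or genes that vary together. Camera recovered the 1 list shifted 2-fold and called 0 of 45 random lists, with genes drawn independently, so this does not cover lists of correlated genes, and 5.1% of 1000 unchanged draws had an exact permutation p under 0.05.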

Results

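Thymic T-cell lymphomas of mice were compared by whether they had responded to genetic reactivation of wild-type p53, as judged by imaging. The comparison asks which transcripts distinguish tumours that resisted restoration from those that responded. There were 8 responding and 4 non-responding tumours, 1 RNA-seq library each. Libraries held 20796860 to 30265753 counts, with 25948770 ± 1955933 in responders (SD, n = 8) and 22261838 ± 1560158 in non-responders (SD, n = 4). The mean was lower in non-responders (exact permutation test, two-sided, p = 0.00404). The groups overlapped, with 24393524 counts in non-responder 4 and 23808086 in responder 5. Mitochondrially encoded mRNAs took 2.03% ± 0.387 of the counts in responders and 1.41% ± 0.166 in non-responders (exact permutation p = 0.00808).

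The first principal component of log2 CPM held 46.2% of the variance and separated most responders from the non-responders. Its mean score was -40.3 in responders and 80.6 in non-responders (exact permutation p = 0.0222, n = 8 and 4). The groups overlapped on it, because responders 2 and 3, at 69.5 and 71.8, lay among the 4 non-responders at 54.8 to 105.6. The second component, with 10.9% of the variance, did not separate the groups (exact permutation p = 0.996).

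**Figure D1:**
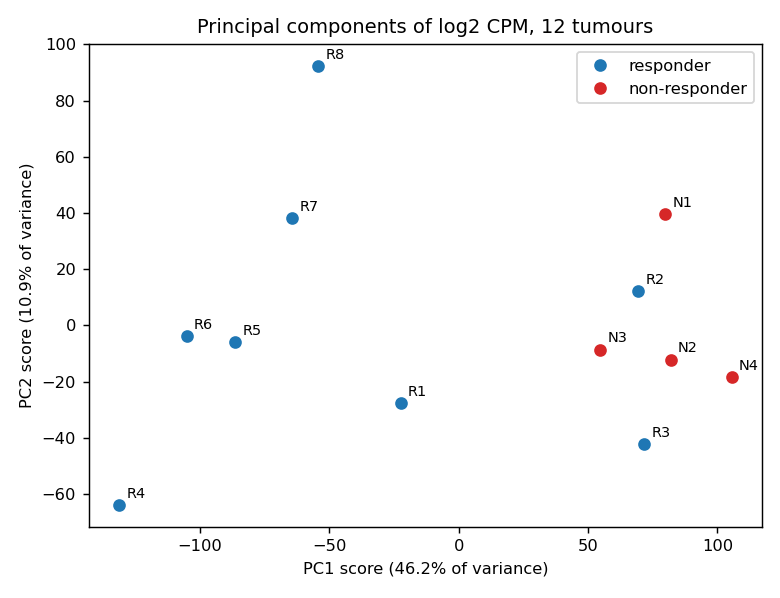
Scores of the 12 tumours on the first (x) and second (y) principal components of log2 CPM, with R for responder and N for non-responder followed by the replicate number. Responders 2 and 3 lie at 69.5 and 71.8 on the first component, within the non-responders' range of 54.8 to 105.6.

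Trp53 itself, the restored gene, had the same mean level in both groups. It stood at 69.3 ± 20.8 CPM in responders (SD, n = 8) and 69.2 ± 4.36 CPM in non-responders (SD, n = 4), with a log2 fold change of 0.00 (SE 0.21, edgeR adjusted p = 0.997) whose sign turned under RLE scaling. Trp53 (ENSMUSG00000059552) lies on chromosome 11 from 69580359 to 69591873 (GRCm38). The counts do not separate transcripts of the restored allele from those of the mutant one. Of the 10 core targets, Mdm2, which encodes the ubiquitin ligase that degrades p53, was at 73.0 ± 13.4 CPM in responders and 111 ± 30 CPM in non-responders. Its log2 fold change was 0.60 (SE 0.19), with an edgeR adjusted p of 0.118 and an exact permutation p of 0.00808 (0.0889 after adjustment over the 11 genes). Bbc3, which encodes the pro-apoptotic protein PUMA, was at 13.6 ± 9.58 CPM in responders and 3.58 ± 1.64 CPM in non-responders (log2 fold change -1.92, SE 0.69, edgeR adjusted p = 0.134). Eda2r, a death-domain receptor gene, had a log2 fold change of -1.38 (SE 0.50, edgeR adjusted p = 0.135), at 1.37 ± 0.699 against 0.522 ± 0.271 CPM. Cdkn1a, the gene of the cell-cycle inhibitor p21, was at 6.71 ± 4.78 CPM in responders and 3.79 ± 3.77 CPM in non-responders (log2 fold change -0.82, SE 0.77). Pmaip1 differed by -0.84 (SE 0.55) and Ccng1 by -0.31 (SE 0.22). Cdkn1a was at -0.47, -0.51 and -1.63 without non-responder 1, 2 and 3, and Pmaip1 at -0.52 and -1.43 without non-responder 2 and 4. Bax, Zmat3, Phlda3 and Sesn2 lay between -0.09 and 0.11. None of the 11 genes passed in edgeR or limma-voom, while DESeq2 called 2 of them, Mdm2 (adjusted p = 0.0342) and Bbc3 (adjusted p = 0.0297). With 1 surrogate variable, a covariate estimated from the data, the signs of Phlda3 (1.01), Pmaip1 (0.76), Bbc3 (0.21) and Ccng1 (0.21) turned. These 4 also turned with the mean of the 13 other-cell scores as a covariate, chosen after seeing the data (Phlda3 to 1.32), as did Eda2r (0.01), and Phlda3 (0.62) and Zmat3 (0.00) with the fibroblast and macrophage scores. In the wider list of p53 targets, 20 of 43 measured genes were higher and 23 lower in non-responders. Adjusted over the list alone 2 passed, Ddit4 (higher) and Ccnd2 (lower). That list did not stand apart from other genes in a shared direction (camera adjusted p = 0.99). Its mean (-0.27) and median (-0.06) were below 0 while camera's direction was upward. In the fry test for change in either direction it was 1 of 21 lists under 0.05 (adjusted p = 0.0285).

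**Figure D2:**
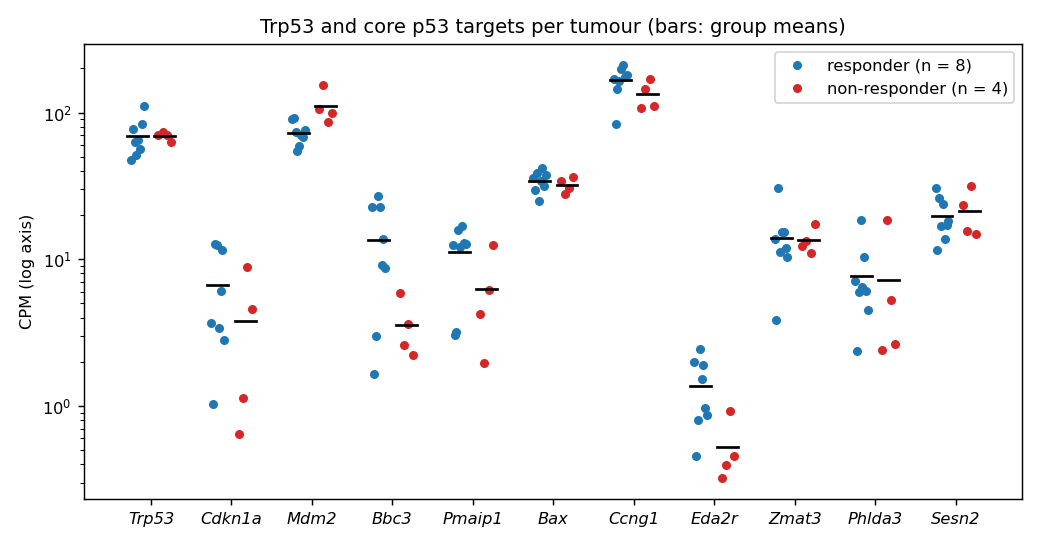
Level of Trp53 and 10 core p53 targets (x) in CPM on a log axis (y), each point a tumour and each bar a group mean over 8 responders or 4 non-responders. Trp53 has means of 69.3 and 69.2 CPM, and Bbc3 spans 1.64 to 26.9 CPM in responders against 2.22 to 5.87 CPM in non-responders.

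No gene passed the threshold in the main test, although many genes leaned the same way. edgeR called 0 of 18612 genes at an adjusted p under 0.05 (lowest 0.0786), and 4428 had an unadjusted p under 0.05 where chance gives 931. Of these 4428, 1438 were higher and 2990 lower in non-responders. This unadjusted count stayed similar in 9 of 12 alternatives and moved in 3. With 1 tumour left out it ran from 3224 to 5534. The CPM of both groups did not overlap for 396 genes, 2.13% of those tested where chance gives 0.404%; 177 of them were higher and 219 lower in non-responders. The number of genes past the adjusted threshold depended on the tool. DESeq2 called 2507 genes, 513 higher and 1994 lower in non-responders (20.5% higher), and limma-voom with quality weights called 1723, 847 higher and 876 lower (49.2% higher). They shared 1135 genes, all 1135 with the same direction. Leaving out responder 3 raised the edgeR count to 5 (Nfkb2, Fsd2, Rab3ip, Zfp618 and Myrfl), leaving out non-responder 1 to 3 (L1td1, Vash2 and 1 identifier with no symbol) and leaving out non-responder 3 to 1 (Fsd2). Zfp618, Myrfl and Vash2 are named here after their values were seen.

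Fsd2, which encodes a protein with fibronectin type III and SPRY domains, had the lowest p of all genes and was higher in non-responders. It was at 4.52 ± 1.01 CPM in responders (SD, n = 8) and 22 ± 11.8 CPM in non-responders (SD, n = 4), without overlap (log2 fold change 2.28, SE 0.30, edgeR adjusted p = 0.0786). Fsd2 (ENSMUSG00000038663) lies on chromosome 7 from 81533308 to 81566944 (GRCm38). Ddit4, which encodes an inhibitor of the growth kinase mTOR and was also on the p53 target list, was at 99.0 ± 21.4 and 233 ± 102 CPM, again without overlap (1.23, SE 0.24). Smpd2, the gene of a neutral sphingomyelinase, was at 18.1 ± 2.12 and 33.5 ± 4.56 CPM (0.89, SE 0.15). It overlaps Mical1 on the opposite strand, so its counts carry the limit given below for Nfkb2. Rab3ip, a gene of vesicle transport, was at 15.5 ± 6.17 and 42.8 ± 9.70 CPM (1.46, SE 0.26), and Thnsl2 at 4.36 ± 2.92 and 25.3 ± 8.97 CPM (2.53, SE 0.51). The other 5 were Gkap1 (1.62), Fam129c (1.36), L1td1 (3.72), Popdc3 (3.39) and Snx31 (2.66), the last 3 below 1 CPM on average in responders. Except for Fsd2, these genes had an edgeR adjusted p of 0.117, and all 10 passed in DESeq2 and limma-voom.

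Among the genes lower in non-responders, 10 of those with the lowest p are given here. Nfkb2, which encodes the p100 subunit of the non-canonical NF-kB pathway, was at 54.0 ± 16.9 CPM in responders and 20.1 ± 2.08 CPM in non-responders, without overlap (log2 fold change -1.43, SE 0.27, edgeR adjusted p = 0.117). Nfkb2 (ENSMUSG00000025225) lies on chromosome 19 from 46304320 to 46312385 (GRCm38) and overlaps Psd on the opposite strand. Psd itself was at 5.68 ± 1.55 and 1.62 ± 0.474 CPM (-1.80, SE 0.33), and since the use of strand in counting is not stated, reads in the overlap cannot be assigned. Slco4a1, an organic anion transporter gene, was at 4.50 ± 2.04 and 0.787 ± 0.257 CPM (-2.51, SE 0.45). Slc5a8, a monocarboxylate transporter gene, was at 2.76 ± 1.37 and 0.535 ± 0.106 CPM (-2.35, SE 0.48). Fyb2 was at 2.80 ± 1.40 and 0.386 ± 0.150 CPM (-2.84, SE 0.53). The membrane mucin gene Muc1 (-2.41), the cardiac and slow-muscle myosin gene Myh7 (-4.48), Fam83b (-2.70), Ces2f (-4.79) and Sec14l4 (-3.47) averaged 1.39 CPM or less in responders. All 10 had an edgeR adjusted p of 0.117 and no overlap between groups, and all passed in DESeq2 and limma-voom.

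Of the 13 scores of other cell types, those of neutrophils, muscle, red cells and thymic epithelium were lower in non-responders. T cells can also express genes of the cytotoxic and NK-cell list, so its score, and the mean of the 13, need not come from other cells alone. The score of the neutrophil list was 2.62 ± 1.67 in responders (SD, n = 8) and -0.18 ± 0.34 in non-responders (SD, n = 4), a difference of -2.80 (exact permutation p = 0.0101). That of the muscle list differed by -2.71 (exact permutation p = 0.00606), of the erythroid list by -2.48 (exact permutation p = 0.0121) and of the thymic epithelial list by -1.47 (exact permutation p = 0.0141). After adjustment over the 13 lists these 4 were at 0.0458 in the permutation test, and the other 9 did not pass. The differences of those 9 were -2.20 for adipocytes, -2.01 for cytotoxic and NK cells, -1.40 for dendritic cells, -1.39 for B cells, -1.34 for endothelium, -1.10 for lung epithelium, -0.96 for plasma cells, -0.65 for macrophages and -0.35 for fibroblasts. With 1 tumour left out, lung epithelium ran from -1.471 to -0.695 and fibroblasts from -0.499 to -0.208. No score passed when any 1 of the 4 non-responders or of responders 1, 4, 5, 6 and 7 was left out, 7 passed without responder 2, and the thymic epithelial score did not pass without responder 8. The medians of the members gave 0 lists as well.

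**Figure D3:**
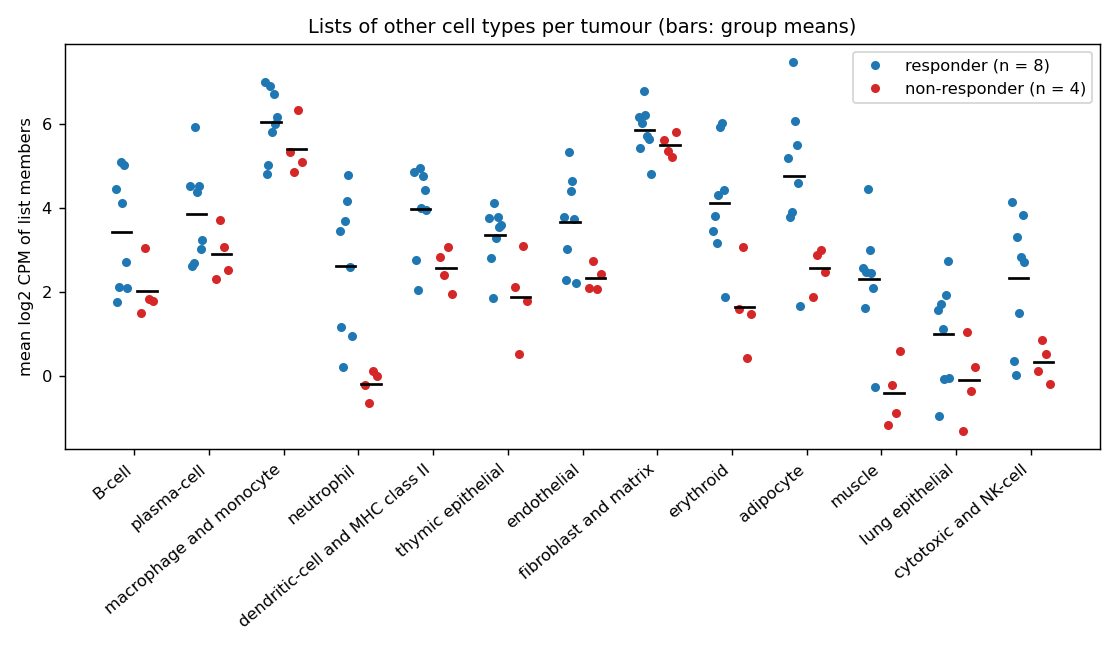
Score of 13 lists of other cell types (x), the mean log2 CPM of the members (y), each point a tumour and each bar a group mean over 8 responders or 4 non-responders. The neutrophil list has means of 2.62 and -0.18, and the fibroblast list of 5.85 and 5.50.

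Within these lists, S100a9, a calcium-binding protein gene of neutrophils, was at 82.9 ± 94.5 CPM in responders and 1.61 ± 1.40 CPM in non-responders (log2 fold change -5.68, SE 1.36, edgeR adjusted p = 0.117), and Ngp at 17.3 ± 23.0 and 0.162 ± 0.0569 CPM. Tnnt2, cardiac troponin T, was at 13.2 ± 18.6 and 0.870 ± 0.683 CPM, and Des, desmin, at 21.7 ± 14.1 and 5.61 ± 2.35 CPM. The fat hormone gene Adipoq was at 42.7 ± 58.0 and 2.70 ± 1.49 CPM and the haem synthesis gene Alas2 at 55.2 ± 41.9 and 6.87 ± 5.22 CPM. Cd74, the invariant chain of MHC class II, was at 551 ± 395 and 123 ± 51.9 CPM, and H2-Aa at 366 ± 294 and 76.3 ± 32.5 CPM. The endothelial gene Vwf was at 72.5 ± 55.0 and 20.3 ± 6.49 CPM, the B-cell factor gene Ebf1 at 18.0 ± 16.6 and 3.52 ± 1.34 CPM, and the matrix gene Dcn at 273 ± 206 and 75.2 ± 29.0 CPM. The cytotoxic-cell genes Nkg7 and Klrk1 were at 10.8 ± 10.6 against 0.505 ± 0.410 CPM and at 10.6 ± 11.6 against 0.834 ± 0.413 CPM. Among thymic epithelial genes, Pax9 was at 4.01 ± 1.91 and 0.982 ± 0.413 CPM, whereas Cldn4, a claudin gene, was higher in non-responders (13.3 ± 9.87 and 46.5 ± 19.6 CPM). The lung transporter gene Slc34a2 was at 2.72 ± 1.36 and 0.610 ± 0.641 CPM. None of these genes passed in edgeR over all genes. Adjusted over the list alone, 12 of 15 neutrophil, 11 of 19 muscle, 13 of 13 adipocyte, 15 of 18 dendritic-cell, 10 of 14 erythroid, 12 of 15 cytotoxic, 11 of 19 endothelial, 10 of 17 B-cell, 3 of 10 lung epithelial and 3 of 25 macrophage genes passed, all lower in non-responders. Of 18 thymic epithelial genes 7 passed as lower and 1, Cldn4, as higher, and none of 30 fibroblast and 10 plasma-cell genes passed. The signs of Ebf1 (0.11) and Dcn (0.03) turned with 1 surrogate variable, and again (0.53 and 0.33) with the mean of the 13 scores as a covariate.

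Of the 46 lists, camera with the preset correlation called 24, of which 18 were lower and 6 higher in non-responders. With an estimated correlation it called 0 (lowest adjusted p = 0.5 with an estimated correlation), and fry also called 0 (lowest adjusted p = 0.0682), with 21 at an adjusted p under 0.05 for change in either direction. The called lists of other cell types were muscle, neutrophil, endothelial, adipocyte, dendritic-cell, erythroid, thymic epithelial, B-cell, cytotoxic, lung epithelial and fibroblast genes, with adjusted p from 2.48e-08 (muscle) to 0.0455 (fibroblast). With an estimated correlation their adjusted p lay between 0.5 and 0.697. The fibroblast list (mean -0.47) was not called without responder 1 (-0.43), 3 (-0.43), 4 (-0.28) or 5 (-0.43) or non-responder 1 (-0.51), 2 (-0.40) or 3 (-0.39), nor the lung list (-1.32) without responder 3 (-1.28) or 7 (-0.99) or non-responder 1 (-1.09). Over the 11 alternatives other than left-out tumours, the lung list lost its call in 7. The fibroblast list lost its call in 4 of the 11 and its mean turned in 2. The B-cell (0.22) and endothelial means (0.04) turned with 1 surrogate variable. The mean of the 13 other-cell scores as a covariate contains these lists. In camera at the preset correlation it gave B-cell (0.90), endothelial (0.49) and fibroblast genes (0.24) as higher in non-responders. The adipocyte mean (0.01) turned without a call. The fibroblast mean (0.02) also turned with its own score among the covariates. The 22 lists not called had camera adjusted p from 0.0526 to 0.99, among them NOTCH signalling (0.975, 10 of 23 genes higher) and MYC and ribosome biogenesis (0.73, 15 of 32 higher). Members of the NOTCH list went both ways. Of its 23 genes, 11 had an unadjusted edgeR p under 0.05, and 3 passed over the list alone, all lower. For change in either direction the fry adjusted p was 0.0322 for NOTCH and 0.284 for MYC.

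**Figure D4:**
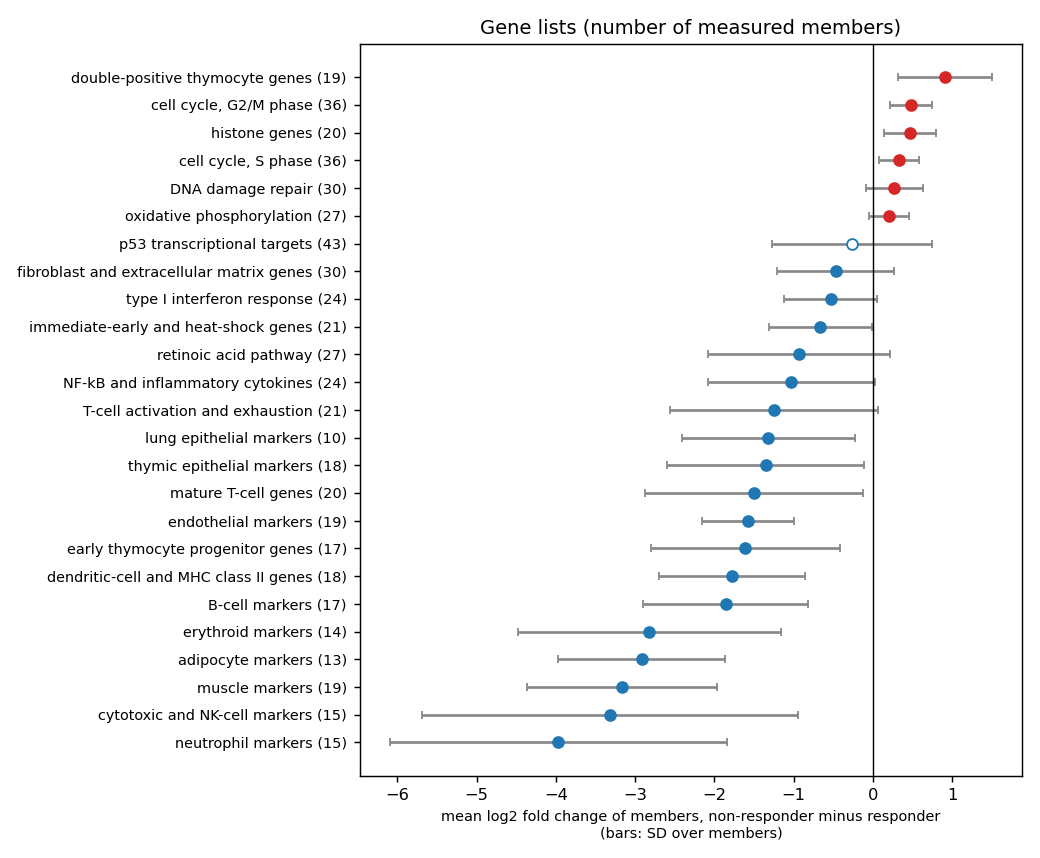
Mean log2 fold change (x, non-responder minus responder) of the members of the 24 lists called by camera at the preset correlation (filled) and of the p53 target list (open); bars are the SD over members and numbers in brackets count measured members. The neutrophil list has the lowest mean (-3.97) and the list of double-positive thymocyte genes the highest (0.91).

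On group means, genes of immature cortical thymocytes were higher, and genes of mature, activated and progenitor T cells lower, in non-responders, but part of the responders resembled the non-responders. Of the 19 genes of double-positive thymocytes (cells with both CD4 and CD8), 18 were higher in non-responders (mean log2 fold change 0.91, camera adjusted p = 2.05e-05, and adjusted p = 0.5 with an estimated correlation). Satb1, a chromatin organiser gene of thymocytes, was at 466 ± 302 CPM in responders and 1034 ± 566 CPM in non-responders, and Cd24a at 121 ± 97.6 and 296 ± 152 CPM; no member passed over the list alone. Without non-responder 1 the list mean was 0.52 and the log2 fold change of Satb1 0.72, from 1.15. The mean log2 CPM of this list was 6.89, 7.12 and 6.40 in responders 1 to 3, within the 5.66 to 7.66 of non-responders. In responders 4 to 8 it was 2.90 to 3.60. Of the 20 mature T-cell genes, 18 were lower, 11 of them passing over the list alone (camera adjusted p = 0.000134, and adjusted p = 0.5 with an estimated correlation). The receptor gene of interleukin 7, Il7r, was at 242 ± 271 and 20.2 ± 11.6 CPM, and the costimulatory gene Icos at 147 ± 130 and 15.3 ± 11.2 CPM. The mean log2 CPM of the mature list was 3.888 and 3.287 in responders 2 and 3, within the 3.185 to 3.96 of non-responders. The early progenitor list had 16 of 17 genes lower (camera adjusted p = 1.13e-05, and adjusted p = 0.5 with an estimated correlation), with Meis1 at 9.51 ± 9.54 and 1.48 ± 0.736 CPM and Tal1 at 3.38 ± 3.66 and 0.421 ± 0.173 CPM. In the T-cell activation list 18 of 21 genes were lower (camera adjusted p = 0.000385, and adjusted p = 0.5 with an estimated correlation), among them Egr3 at 5.42 ± 5.85 and 0.264 ± 0.180 CPM and Cd274, which encodes PD-L1, at 33.7 ± 19.9 and 9.94 ± 2.98 CPM. The scores of other cell types were lower in the same tumours, with differences of -2.80 for neutrophils and -2.71 for muscle. With 1 surrogate variable the means of the mature T-cell (0.02) and activation lists (0.20) turned, as did the sign of Icos (0.27). The mean of the progenitor list (0.14) and the sign of Tal1 (0.17) turned with the mean of the 13 other-cell scores as a covariate.

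The responders differed among themselves for these genes. Rag1, which encodes a recombinase subunit of cortical thymocytes, was at 895, 1200, 1260, 0.456, 2.91, 0.51, 0.41 and 0.714 CPM in responders 1 to 8 and 1500, 168, 1760 and 1260 CPM in non-responders 1 to 4. Notch1, a receptor gene of T-cell commitment, was at 778, 1910, 1500, 104, 112, 128, 73.4 and 78 CPM in responders 1 to 8 and 6490, 4480, 900 and 1170 CPM in non-responders 1 to 4. Both genes were chosen after their values were seen. The mean of the double-positive list (-0.57) and the sign of Rag1 (-2.56) turned with 1 surrogate variable, and again (-0.03 and -0.46) with the mean of the 13 scores as a covariate.

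**Figure D5:**
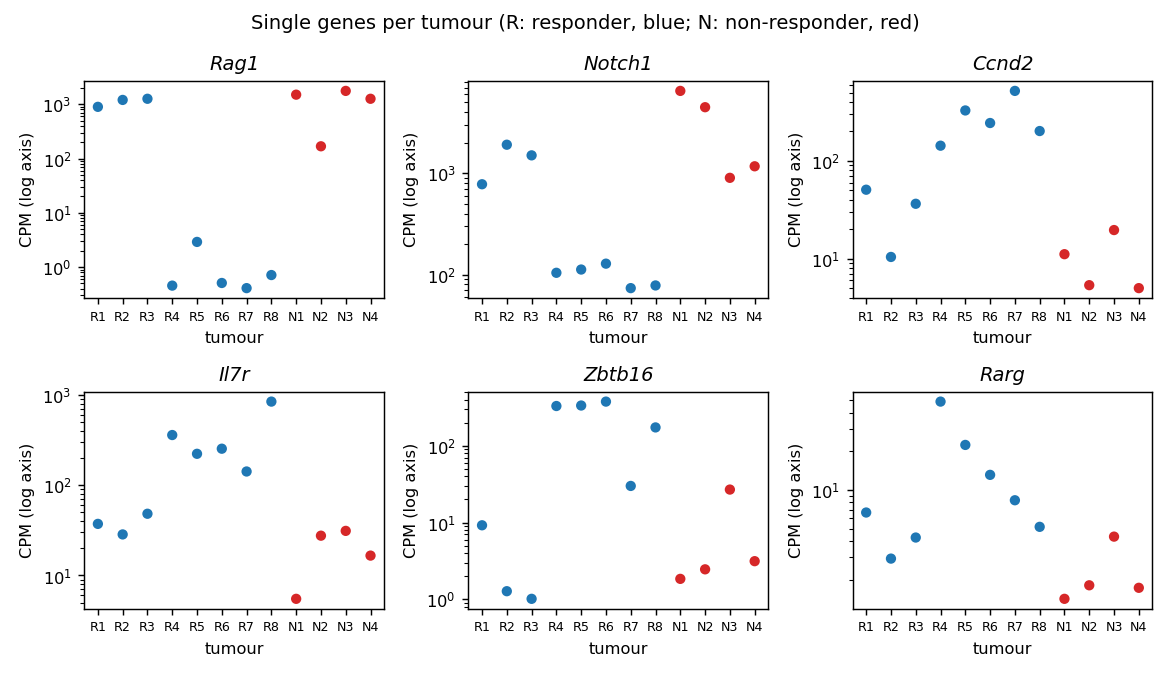
CPM on a log axis (y) of 6 genes in each tumour (x), with R for responder and N for non-responder followed by the replicate number. Among responders, Rag1 ranges from 0.41 to 1260 CPM.

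On group means, cell-cycle genes leaned higher in non-responders by a small amount, with a direction that turned in 2 of 3 covariate models. Of 36 genes of the G2/M phase, 35 were higher (mean log2 fold change 0.48, camera adjusted p = 5.33e-08, and adjusted p = 0.512 with an estimated correlation). The mitotic genes Cdc25c and Prc1 were at 11.5 ± 5.15 against 21.1 ± 3.56 CPM and at 91.7 ± 40.5 against 159 ± 24.8 CPM. Of 36 S-phase genes, 33 were higher (0.33, camera adjusted p = 9.26e-05, and adjusted p = 0.621 with an estimated correlation), with the ribonucleotide reductase gene Rrm2 at 124 ± 47.9 and 224 ± 101 CPM and the replication helicase gene Mcm7 at 302 ± 113 and 498 ± 174 CPM. Histone genes (19 of 20 higher, mean 0.46), DNA repair genes (24 of 30, mean 0.27) and oxidative phosphorylation genes (20 of 27, mean 0.20) had camera adjusted p of 0.000361, 0.0086 and 0.0086. With an estimated correlation their adjusted p were 0.621, 0.596 and 0.621. The linker histone gene Hist1h1b was at 617 ± 247 and 1002 ± 275 CPM, the repair genes Fanca and Parp1 at 31.9 ± 12.7 against 64.8 ± 16.5 CPM and at 270.0 ± 99.9 against 447 ± 43.2 CPM, and the ATP synthase gene Atp5b at 1141 ± 349 and 2028 ± 725 CPM. No member of these 5 lists passed over its list alone. Responders 2 and 3 resembled the non-responders for the first 3 lists. Their mean log2 CPM was 7.356 and 7.07 for G2/M, against 6.737 to 7.315 in non-responders. For S phase it was 6.973 and 6.851, against 6.489 to 7.229, and for histones 8.614 and 8.159, against 7.57 to 8.774. Leaving out non-responder 4 took the means to 0.13 for S phase and 0.23 for histones, and DNA repair (0.21) and oxidative phosphorylation (0.12) were then not called, the latter not without non-responder 2 either (0.14). Rrm2 went from 0.85 to 0.52 and Mcm7 from 0.72 to 0.45 without non-responder 4. With 1 surrogate variable the means of all 5 lists turned, to -0.20 for G2/M, -0.26 for S phase, -0.35 for histones, -0.09 for DNA repair and -0.02 for oxidative phosphorylation. In that model camera at the preset correlation called 3 of them lower in non-responders, S phase (adjusted p = 0.000551), histones (0.000983) and G2/M (0.00505). The covariate models were not run with an estimated correlation, which removed every call in the main test, so these calls carry the same limit. The mean of the 13 other-cell scores as a covariate, chosen after seeing the data, gave S phase (6.45e-05), G2/M (0.00747), histones (0.0128) and DNA repair (0.0258) as lower too, while oxidative phosphorylation (mean 0.04) kept its direction. That other-cell score was 2.48 or more in every responder and 2.28 or less in every non-responder, so its model cannot separate it from the group. The sign of Hist1h1b turned in both models (-0.03 and -0.07). In the model with the fibroblast and macrophage scores as covariates all 5 means stayed above 0, and camera called only G2/M (mean 0.19), as higher in non-responders. Over all alternatives, in either direction, adjusted p ran from 2.3e-06 to 0.621 for S phase, 2.74e-10 to 0.512 for G2/M, 2.68e-05 to 0.621 for histones and 0.000702 to 0.596 for DNA repair, so the direction depended on the model.

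On group means, the lists of NF-kB, of immediate-early and heat-shock and of type I interferon genes were lower in non-responders. Of the 24 NF-kB genes, 20 were lower, 9 of them passing over the list alone and 1 of the higher genes doing so (camera adjusted p = 0.00022, and adjusted p = 0.5 with an estimated correlation). Besides Nfkb2, the subunit gene Relb was at 26.5 ± 13 CPM in responders and 6.6 ± 1.18 CPM in non-responders, and the lymphotoxin gene Ltb at 118 ± 90.4 and 15.1 ± 5.16 CPM. Of 21 immediate-early and heat-shock genes, 16 were lower (camera adjusted p = 0.00253, and adjusted p = 0.5 with an estimated correlation), among them Klf6 at 78.3 ± 31.4 and 34.3 ± 6.12 CPM and Hspa1b at 6.67 ± 2.91 and 2.67 ± 0.874 CPM. Of 24 type I interferon genes, 20 were lower (camera adjusted p = 0.00607, and adjusted p = 0.621 with an estimated correlation), with Oasl2 at 22.1 ± 10.3 and 8.89 ± 5.09 CPM. The mean of this list (-0.54) was -0.96 without non-responder 3, and -0.38 and not called without non-responder 4. Over the 11 alternatives other than left-out tumours, the NF-kB list kept its direction but lost its call in 4, with adjusted p (camera or fry) from 6.33e-05 to 0.818. The immediate-early and the interferon list each lost theirs in 3. The mean log2 CPM of the NF-kB list was 2.682 and 2.442 in responders 2 and 3, within the 2.054 to 2.809 of non-responders. Ltb was at 13.3 and 7.85 CPM there, within their 7.4 to 18.6 CPM. For the interferon list non-responder 3, at 4.44, lay within the 3.683 to 4.821 of responders. The immediate-early list did not overlap, at 3.744 or more in responders and 3.609 or less in non-responders. Hspa1b has a near-identical copy, so its counts are uncertain. The sign of Ltb turned with 1 surrogate variable (0.40), and other-cell scores were lower in the same tumours (neutrophil difference -2.80).

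Genes of the retinoic acid pathway were mostly lower in non-responders on group means, but responders 2 and 3 did not differ from them. The mean log2 CPM of the list was 1.327 and 1.879 in these 2 responders and 1.433 to 1.88 in non-responders. Of 27 measured genes, 22 were lower and 5 higher (mean log2 fold change -0.93, camera adjusted p = 0.00286, and adjusted p = 0.5 with an estimated correlation). Over the list alone 7 passed, 5 lower and 2 higher, which is not independent evidence, since the list was chosen with the study in mind. Rarg, which encodes retinoic acid receptor gamma, was at 13.9 ± 15.4 CPM in responders (SD, n = 8) and 2.32 ± 1.35 CPM in non-responders (SD, n = 4), with a log2 fold change of -2.59 (SE 0.79, edgeR adjusted p = 0.118). DESeq2 gave Rarg an adjusted p of 0.00675 and limma-voom one of 0.0516. Per tumour, Rarg was at 48.7 CPM in responder 4 and 5.16 to 22.4 CPM in responders 1 and 5 to 8. In responders 2 and 3 it was at 2.92 and 4.26 CPM, within the 1.42 to 4.33 CPM of non-responders. Rarg (ENSMUSG00000001288) lies on chromosome 15 from 102234938 to 102257517 (GRCm38). Lrat, which encodes the enzyme that stores retinol as esters, was at 5.03 ± 5.97 and 0.414 ± 0.239 CPM, and Rarres2, a chemerin gene induced by retinoids, at 9.91 ± 6.34 and 2.61 ± 0.695 CPM. Stra6, the gene of a retinol uptake receptor, was at 2.05 ± 0.725 and 8.22 ± 8.58 CPM (2.0, SE 0.60), with 1.17 to 3.04 CPM in responders and 0.688, 9.51, 2.9 and 19.8 CPM in non-responders 1 to 4. Its log2 fold change was 1.09 without non-responder 4, and its adjusted p was 0.0189 in DESeq2 and 0.167 in limma-voom. With the mean of the 13 other-cell scores as a covariate, chosen after seeing the data, the Rarg log2 fold change was -0.08, and the mean of the list (0.08) and the sign of Rarres2 (0.10) turned. With 1 surrogate variable the mean of the list (0.17) and the sign of Lrat (0.29) turned.

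Regulators of apoptosis and genes of T-cell lymphoma went both ways. Of the BCL2 family, the 5 measured anti-apoptotic genes were lower in non-responders (mean log2 fold change -0.86, camera adjusted p = 0.078, not passing), with Bcl2a1b at 7.51 ± 4.58 and 1.67 ± 0.702 CPM and Bcl2 at 32.7 ± 18.6 and 14.6 ± 8.81 CPM. Bcl2a1b has close paralogs, so its counts are uncertain. Of 10 pro-apoptotic genes, 5 were higher and 5 lower (camera adjusted p = 0.49, and fry adjusted p = 0.0285 for change in either direction). Bmf was at 36.3 ± 11.9 and 75.8 ± 28.7 CPM, without overlap (1.06, SE 0.28, edgeR adjusted p = 0.117), and was the 1 gene that passed over the list alone. Bid was at 44.2 ± 23.6 and 85.4 ± 39.3 CPM. The signs of Bcl2a1b (0.19) and Bid (-0.13) turned with 1 surrogate variable, and that of Bcl2 (0.32) with the mean of the 13 other-cell scores as a covariate. Bid went from 0.95 to 0.60 without non-responder 4. Among lymphoma genes, the cyclin gene Ccnd2 was at 192 ± 173 CPM in responders and 10.3 ± 6.85 CPM in non-responders (-4.22, SE 0.99, edgeR adjusted p = 0.117). The kinase gene Pim1 was at 30.4 ± 9.88 and 14.7 ± 3.89 CPM and Mycn at 1.05 ± 1.43 and 0.0581 ± 0.0225 CPM. Tigar, a p53 target of glycolysis, was at 13.5 ± 5.54 and 6.32 ± 0.956 CPM, without overlap (-1.09, SE 0.33). The list of T-lymphoma genes had 17 of 32 genes higher (camera adjusted p = 0.613, and fry adjusted p = 0.0322 for change in either direction).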

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

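Tests of the share of other cells, of neighbouring tissue, of Rarg against the other-cell score and of dilution were chosen after the results were seen; the thinning test, the Rag1 covariate, the innate-like marker test and the other splits were set out before theirs. Within-group outliers were sought in 196 groups of values (named genes in log2 CPM, scores, and library measures), and 10 had a tumour far from the rest of its group, where chance gives about 9.8.

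Library measures set responders 4 and 6 apart. Responder 4 had the deepest library, at 30265753 counts against 26580041 for the next responder, and the highest mitochondrial mRNA share, 2.89% against 2.22%. Responder 6 had the lowest share of the non-polyadenylated RNAs Rn7sk, Rpph1 and Rmrp, 3.25% against 4.96%. Responder 2 had the lowest Ccng1, 6.39 log2 CPM against 7.17 for the next responder. Responder 3 had the highest Rab3ip, 4.91 against 3.95. Non-responder 1 had the lowest L1td1, -1.69 against 2.92, and the highest Mycn, -2.53 against -2.95. Non-responder 2 had the lowest Rag1, 7.39 against 10.3. Non-responder 4 had the lowest Ltb, 2.90 against 4.08, and the highest Ces2f, -2.99 against -3.63, the latter near the floor of the scale.

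Of the 13 scores of other cell types, 4 passed as lower in non-responders. Library depth is argued against, since the mean difference over the 13 lists was -1.60 as deposited and -1.58 after thinning to the smallest library. A lower share of all other cells alike stays open, because the differences of the 13 scores lay 2.45 log2 units apart from lowest (neutrophils) to highest (fibroblasts), where all splits of the tumours had a median of 1.70 (exact permutation p = 0.0808). Neighbouring fat and muscle in the tumour piece stays open as well: all 32 measured adipocyte and muscle genes were lower in non-responders, which restates the pattern and does not test it, the most abundant being Ttn (393 ± 274 and 135 ± 126 CPM) and Cfd (218 ± 324 and 19.1 ± 9.69 CPM; SD, n = 8 and 4). A response to p53 restoration that changes which cells enter the tumour stays open as untested, because the labels give no tumour size at harvest.

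Rarg was lower in non-responders on group means. RNA from other cells in the tumour piece stays open as a source. The log2 fold change went from -2.59 (SE 0.795) to -0.0827 (SE 0.57) with the mean other-cell score as covariate, chosen after seeing the data. That score was 2.48 or more in every responder and 2.28 or less in every non-responder, so the model cannot separate it from the group. Within the 8 responders, the single such relation computed, Rarg followed that score (Pearson r = 0.848, exact permutation p = 0.00791; Spearman rho = 0.857, exact permutation p = 0.0107). Without the 2 responders farthest from the median score r was 0.78. The T-cell stage as read from Rag1 is not settled. With log2 CPM of Rag1 as covariate the fold change was -1.10 (SE 0.722), between both bounds set for that test. Unlike the other-cell score, Rag1 did not separate the groups. Responders 1 to 3 had it at 895 to 1260 CPM, within the 168 to 1760 CPM of non-responders. No model held both covariates, so stage was not told apart from a cellular source.

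Rag1 stood at separate levels among the responders. Dilution of tumour RNA by other cells is argued against, because the score of the T-cell receptor list spanned 1.29 log2 units over the 12 tumours and Rag1 spanned 11.8. A candidate explanation is an innate-like T-cell programme in part of the responders. The score of 14 markers of such cells, written down before their values were seen, was 4.21 ± 0.872 in responders (SD, n = 8) and 3.19 ± 0.399 in non-responders (SD, n = 4), a difference of -1.03 (exact permutation p = 0.0646), which misses the threshold. The test pools responders with high and low Rag1, so it cannot decide on a programme in part of them, which stays open. Several of these markers are also used by other leukocytes, and this score and the mean other-cell score were both highest in responder 4 (5.62 and 4.88) and both lowest in non-responder 1 (2.74 and 1.75).

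Other splits of the 12 tumours into 8 and 4 were drawn with the real one included. The unadjusted edgeR count of 4428 was reached by 4 of 100 splits, with a highest other of 6526 and a median other of 760, a share under 0.05. Only some of the possible splits were drawn, and no adjustment was made over the counts compared here. The count is therefore unusual among the splits, but chance is not excluded for it. The adjusted edgeR count of 0 (highest other 2978) and the count of 0 core p53 genes (highest other 1) were reached by all 100, as any split must reach 0, so these say nothing about chance. The 24 lists called by camera were reached by 17 of 100 splits (highest other 33, median other 16), so chance is not excluded. The DESeq2 count of 2507 was reached by 2 of 50 splits (highest other 2915) and the limma-voom count of 1723 by 3 of 50 (highest other 5863). The first share is under 0.05 and the second is not. Neither tool was run on the splits with unadjusted edgeR counts of 6526 and 5778, so chance is not excluded for either count. The split with 2978 edgeR genes set responders 4, 5, 6 and 8 against the rest, where the real split gave 0, which points to a structure of the samples other than the groups.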

How the results depend on the processing

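The covariate made of the 13 other-cell scores was chosen after seeing the data; the other alternatives were set beforehand. The cause of each change was not tested unless stated. Outside the alternative with an estimated correlation, camera was run at the preset correlation only. No paired analysis was possible because the labels number no replicates.

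The edgeR count of 0 genes was the same under RLE and upper-quartile scaling, without a filter, with 1 CPM in 4 libraries, without robust dispersion, with each covariate, without the receptor-segment, mitochondrial, haemoglobin and sex-linked genes, and after thinning. It was 2507 in DESeq2, 1723 in limma-voom and 1 (Fsd2) at a threshold of 0.1, which follows from the looser threshold, and 0 to 5 with 1 tumour left out. The 24 lists became 13 with 1 surrogate variable, 0 with an estimated correlation and 0 with fry, 22 to 26 with 1 tumour left out, and 17 to 25 otherwise. The 0 core p53 genes became 2 in DESeq2, 0 to 0 with 1 tumour left out, and 0 otherwise. The 4 other-cell scores that passed stayed 4 with a prior count of 0.5 and RLE scaling and became 0 with medians and 0 to 7 with 1 tumour left out.

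Trp53, near 0, turned to 0.018 in DESeq2, 0.015 with RLE, 0.048 in limma-voom and 0.045 without a filter, and ran from -0.053 to 0.125 with 1 tumour left out. Left-out ranges that crossed 0 were -0.202 to 0.211 for Zmat3, -1.149 to 0.235 for Phlda3, -0.122 to 0.255 for Sesn2 and -0.218 to 0.032 for the pro-apoptotic BCL2 list. Zmat3 turned to 0.054 in limma-voom.

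With 1 surrogate variable the log2 fold change turned for Bbc3 (0.212), Bcl2a1b (0.189), Bid (-0.13), Ccng1 (0.212), Dcn (0.028), Ebf1 (0.112), Hist1h1b (-0.034), Icos (0.268), Lrat (0.294), Ltb (0.399), Phlda3 (1.006), Pmaip1 (0.762) and Rag1 (-2.564). List means turned for B cells (0.22), anti-apoptotic (0.022) and pro-apoptotic BCL2 genes (0.309), DNA repair (-0.085), T-cell activation (0.196), G2/M (-0.199), S phase (-0.257), double-positive thymocytes (-0.571), endothelium (0.044), histones (-0.353), mature T cells (0.021), oxidative phosphorylation (-0.022), p53 targets (0.026) and retinoic acid (0.17). Camera called S phase (adjusted p = 0.000551), histones (0.000983) and G2/M (0.00505) in this opposite direction, and none of the other turned lists.

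With the mean of the 13 other-cell scores as covariate, turned values were Bbc3 (0.077), Bcl2 (0.323), Ccng1 (0.087), Dcn (0.328), Ebf1 (0.53), Eda2r (0.015), Hist1h1b (-0.067), Phlda3 (1.319), Pmaip1 (0.218), Rag1 (-0.456), Rarres2 (0.095) and Tal1 (0.174). List means turned for B cells (0.901), pro-apoptotic BCL2 genes (0.354), DNA repair (-0.196), adipocytes (0.006), G2/M (-0.235), S phase (-0.323), double-positive thymocytes (-0.03), early progenitors (0.144), endothelium (0.489), fibroblasts (0.235), histones (-0.305), p53 targets (0.009) and retinoic acid (0.084). For the other-cell lists this follows in part from the covariate, which contains them. The covariate was 2.48 or more in every responder and 2.28 or less in every non-responder, so the model cannot separate it from the group. Camera called S phase (adjusted p = 6.45e-05), G2/M (0.00747), histones (0.0128) and DNA repair (0.0258) in the opposite direction, and B-cell (3.74e-05), endothelial (0.0155) and fibroblast genes (0.0286) as well. Over all alternatives, in either direction, adjusted p ran from 2.3e-06 to 0.621 for S phase, 2.74e-10 to 0.512 for G2/M, 2.68e-05 to 0.621 for histones, 0.000702 to 0.596 for DNA repair, 2.11e-05 to 0.596 for B cells, 2.47e-08 to 0.852 for endothelium and 0.0286 to 0.948 for fibroblasts. With the fibroblast and macrophage scores as covariates Phlda3 (0.615), Zmat3 (0.003), the pro-apoptotic BCL2 list (0.211) and the fibroblast list (0.021, part of the covariate) turned.

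Fsd2 kept its direction, between 2.075 and 2.353 over the alternatives and 1.9 to 2.535 with 1 tumour left out, with adjusted p from 2.38e-08 to 0.69. Depth limits genes such as Ces2f and Sec14l4, which averaged under 0.6 CPM in responders.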

Other observations

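The tests in this part were chosen after the results were seen, except that of the innate-like markers, and so were the genes. Zbtb16, which encodes PLZF, a transcription factor of innate-like T cells, was at 9.2, 1.27, 1.01, 331, 336, 378, 30 and 174 CPM in responders 1 to 8 and 1.84, 2.45, 26.9 and 3.13 CPM in non-responders 1 to 4. Il18r1, an interleukin 18 receptor gene, was at 21, 2.3, 1.77, 145, 222, 112, 42.5 and 186 CPM in responders 1 to 8 and 1.7, 1.32, 9.43 and 1.59 CPM in non-responders 1 to 4, and Cxcr6, a chemokine receptor gene, at 21.9, 3.08, 2.02, 179, 73.3, 30.5, 41.1 and 62.8 CPM in responders 1 to 8 and 2.62, 2.16, 6.44 and 2 CPM in non-responders 1 to 4. Dntt, which encodes the polymerase that adds bases at receptor joints, was at 608, 961, 581, 0.26, 1.06, 0.578, 1.08 and 0.476 CPM in responders 1 to 8 and 687, 19.1, 550 and 352 CPM in non-responders 1 to 4. Rag2, the partner of Rag1, was at 43.6, 37.6, 18.1, 0.0651, 0.0819, 0.034, 0.0372 and 0.119 CPM in responders 1 to 8 and 44.3, 10.2, 38 and 19.2 CPM in non-responders 1 to 4. No test was made between tumours sorted by these genes.

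In each tumour 1 T-cell receptor beta variable segment led, by its share of counts over the 20 Trbv segments in the table. Trbv13-2 led in responders 4, 5, 6 and 7, with 82.1% (Wilson 95% interval 80.3 to 83.8), 97.6% (96.9 to 98.1), 77.5% (75.9 to 79.0) and 97.2% (96.6 to 97.7). Trbv16 led in responder 8 with 99.0% (98.8 to 99.2). Trbv3 led in responder 1 with 75.4% (74.5 to 76.2), Trbv13-3 in responder 2 with 61.6% (60.3 to 62.8) and Trbv31 in responder 3 with 74.8% (73.4 to 76.1). Among non-responders, Trbv5 led in 2 with 98.3% (98.0 to 98.6) and in 4 with 97.8% (97.4 to 98.0), Trbv13-1 in 1 with 95.9% (95.5 to 96.3), and Trbv19 in 3 with 47.8% (45.8 to 49.7). The totals behind these shares were 1840 to 12390 counts, and reads of related segments can be exchanged in counting.

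A hypothesis is that some of the responders may be lymphomas of innate-like T cells, such as natural killer T cells, which use PLZF and often the Trbv13-2 segment. Rag1, Rag2, Dntt, Zbtb16, Il18r1 and Cxcr6, all chosen after their values were seen, each set responders 4 to 8 apart from the rest. Rag2 was at 0.119 CPM or less in responders 4 to 8 and 10.2 CPM or more elsewhere. Il18r1 was at 42.5 CPM or more against 21 CPM or less. The gap was narrow for Zbtb16: responder 7, led by Trbv13-2, had it at 30 CPM, near the 26.9 CPM of non-responder 3. The leading segment did not follow this split in full, since responder 8, with Zbtb16 at 174 CPM, was led by Trbv16. The test of 14 other markers cannot settle the hypothesis, since it compared the response groups and pooled responders with high and low Rag1. The score of these markers differed by -1.03 between non-responders and responders. Per tumour the score was 5.62, 4.55, 4.79, 4.35 and 3.59 in responders 4 to 8, 4.53, 2.97 and 3.30 in responders 1 to 3, and 2.74, 3.32, 3.67 and 3.02 in non-responders 1 to 4. Responder 1 scored between responders 5 and 7 with Zbtb16 at 9.2 CPM, against the hypothesis that this score marks the tumours with high Zbtb16. The most abundant of these markers in responder 4 were Blk (250 CPM), Tmem176b (212 CPM), Id2 (199 CPM) and Maf (173 CPM). The receptor alpha segment that would identify natural killer T cells was not analysed here.

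Rn7sk, Rpph1 and Rmrp, small RNAs without a poly(A) tail, together took 3.25% to 6.37% of the counts, although the kit named in the labels is for mRNA.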
